A study of Nasonia vitripennis with 70 samples.

How the data were processed

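The gene table used for testing holds expected counts deposited by the authors for 14621 genes in 70 libraries, and a companion table by the authors holds TPM for 14613 genes. Per the submitters' processing notes, reads were aligned with STAR 2.7.11a and quantified with RSEM 1.3.1; the genome build used for that step is not given in the sources used here. Expected counts were rounded to whole numbers before testing, since 18.2% of the values were not whole. The 8 genes found only in the count table held a summed count of 2.92 over all libraries. TPM columns summed to between 999999.4 and 1000001. All 14621 symbols were found in the reference gene table of assembly Nvit_psr_1.1, which served for names and for the order of neighbouring genes only. No pair of libraries within a group was a copy of another (lowest chi-square per gene between 2 libraries of a group 5.11). RSEM divides reads among similar sequences, so close paralogues within the odorant receptor, cytochrome P450 and serine protease families may share reads, and a value for a single member carries that uncertainty.

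Libraries were poly-A RNA of heads or abdomens taken 1 day after emergence. Replicates are known by library codes alone. Which head and which abdomen came from the same animal, and how many animals entered a library, is not given in the sources used here, so heads and abdomens were treated as independent. Females were collected at F2 and F14 and males at F5 and F15. Generation therefore cannot be separated from the date of collection and handling, and the comparison of the sexes sets males of F5 and F15 against females of F2 and F14.

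Counts were tested with edgeR 4.0.16 (TMM size factors, filterByExpr, quasi-likelihood F test) in R 4.3.3. Heads (35 libraries, 8 groups, 11785 genes kept, common biological coefficient of variation 0.341, residual degrees of freedom 27) and abdomens (35 libraries, 8 groups, 12308 genes, 0.515, 27) had separate fits. Contrasts of tissue were drawn from a fit of all female libraries (34 libraries, 12114 genes, 0.345, 26) and a fit of all male libraries (36 libraries, 12387 genes, 0.503, 28). P values were adjusted by Benjamini-Hochberg within each contrast, and a gene was called at an adjusted p below 0.05. Every p value beside a gene is an adjusted p from edgeR unless another tool is named. Generation and sex contrasts average the 2 groups on each side with equal weight, and a contrast of contrasts tests whether the effect of ploidy differs between generations. Levels are counts scaled to the effective library size (CPM) as mean ± SD over libraries, and fold changes are log2 with a standard error (SE). Groups of 4 or 5 libraries give SDs that are themselves imprecise.

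Genes were named by a rule. It had been laid down for genes with a description, and since the tables carry symbols alone it was applied to the 829 symbols that are not of the LOC form. The rule takes up to 6 genes per direction that passed at both generations, up to 3 or 4 per direction and contrast with the largest change and no overlap between libraries (these kinds with a mean of at least 5 CPM in a compared group), and at any level up to 4 members of each list described, and the sex determination genes everywhere. Some genes that the rule takes are not reported. A few LOC genes outside the rule are said to be chosen after their values were seen. Numbers of genes moving together were taken from 26 lists: oxidative phosphorylation; mitochondrial protein import; ribosome and translation; mRNA splicing; chaperones; DNA replication and repair; cell cycle and mitosis; chromatin modifiers; germ line and embryo patterning; dynein and dynactin; odorant receptors; gustatory receptors; ion channels and synapse; peptide and steroid hormone signalling; hexamerins and lipid storage; major royal jelly protein-like; yellow family; immunity; serine proteases; serine protease homologs; cytochrome P450; glutathione S-transferases; carboxylesterases; cuticle and chitin; muscle; sex determination. Some themes had been set for gene descriptions. Others, and all members, came from symbols after gene names were seen and before any test. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over 184 tests for the ploidy contrasts and 276 for the others, and again with the correlation estimated from the data. With the estimated correlation no list passed, and each preset p value is printed with its estimated counterpart. Because members of a list rise and fall together from library to library, the preset p values understate the uncertainty.

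Overlap of calls between generations was tested with Fisher's exact test, and clustering of called genes along chromosomes with 10000 permutations of gene positions. Each contrast was also recomputed on divisions of its own libraries that mix the compared groups, up to 40 per contrast, to see whether they call as many genes.

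Power was measured on counts simulated with the means, library sizes and dispersions of the real libraries. Only 100 genes changed 2-fold and 100 changed 4-fold differed between groups. For ploidy in heads edgeR recovered 47 to 56 of 100 at 2-fold and 73 to 80 at 4-fold. In abdomens it recovered 24 to 28 and 52 to 57. For the contrasts of contrasts it recovered 27 and 25 at 2-fold in female and male heads, and 5 and 6 in their abdomens. False calls numbered 0 to 14 per contrast (highest share 13 of 124 calls). Factors shared by genes were not simulated, so this is no error rate of the real libraries.

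The groups, the contrasts, the edgeR model, the threshold and 7 kinds of alternative (DESeq2 1.42.0, RLE size factors, no low-count filter, the compared groups alone, limma-trend on log2(TPM + 1), 2 surrogate variables from sva 3.50.0, and leaving out each library in turn) were set before the data were examined. Added after the data had been seen were a fit without 8 libraries with unusual head, muscle or cuticle transcripts (the doubted libraries C46, C69, C81, C82, C86, C87, C91, C92), a head fit with log2 Or1 as a covariate, list tests without C46 or C69, generation in each ploidy alone, and heads and abdomens joined by code.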

Results

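Poly-A RNA of heads and of abdomens was sequenced from the WGDL line of the parasitoid wasp Nasonia vitripennis, a neo-polyploid line made by colchicine-induced genome duplication. Nasonia is haplodiploid, and the line holds diploid and triploid females beside haploid and diploid males. Each tissue has 8 groups. Females of F2 were diploid (n = 4) or triploid (n = 5), and females of F14 diploid (n = 4) or triploid (n = 4). Males of F5 were haploid (n = 5) or diploid (n = 5), and males of F15 haploid (n = 4) or diploid (n = 4). Library totals lay between 12.2 and 25.1 M counts (M, mega). F14 triploid heads had 12.2 to 16.1 M against 16.3 to 23.1 M in F14 diploid heads. F14 triploid abdomens had 12.3 to 17.8 M against 17.7 to 25 M in F14 diploid abdomens. In the other groups totals ran from 17.2 to 24.6 M (F2 heads), 20.5 to 24.7 M (F2 abdomens), 15.6 to 23.6 M (F5 heads), 16.8 to 25.1 M (F5 abdomens), 14.3 to 19.3 M (F15 heads) and 13.4 to 21 M (F15 abdomens). The leading principal component held 71.4% of the variance among abdomens and 23.3% among heads.

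**Figure D1:**
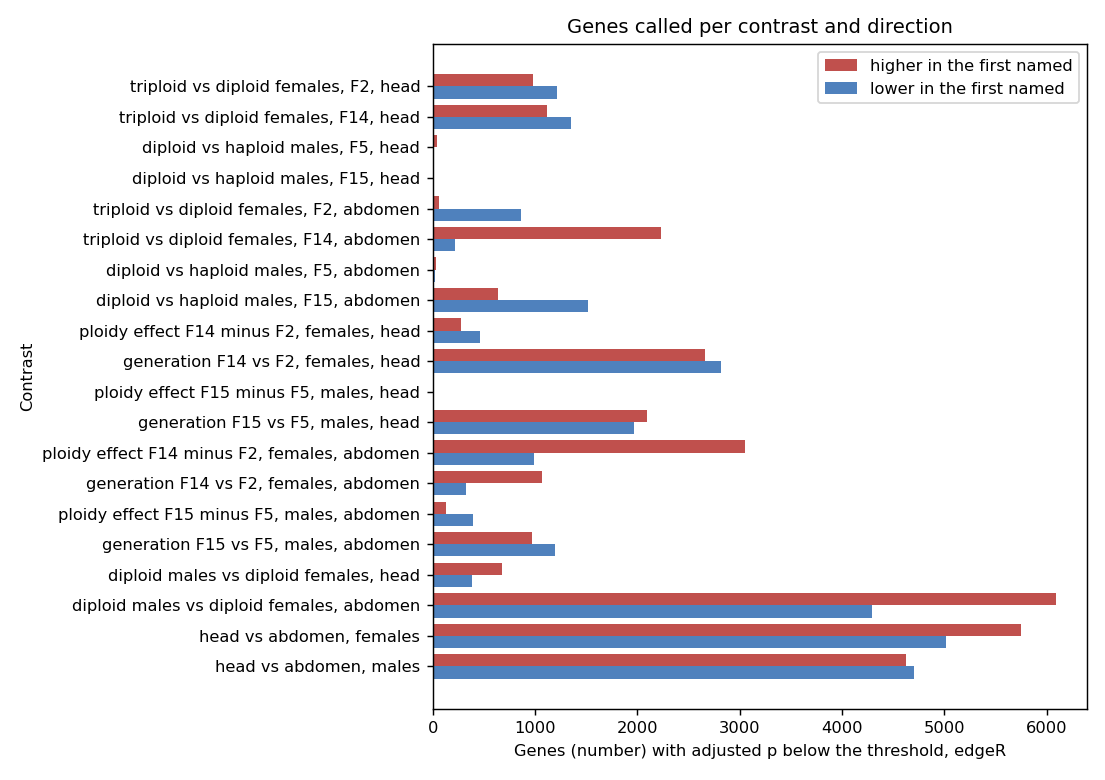
Bars give the number of genes with an edgeR adjusted p below 0.05 in each contrast, split by direction. The longest stand for the abdomens of the sexes (10386 genes) and for the tissues (10768 genes in females), the shortest for the difference of effects in male heads (1 gene).

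Heads of triploid and diploid females were compared to ask which transcripts change when an additional chromosome set is present. Odorant receptors, the ligand-gated channels of antennal sensory neurons, were lower in triploids at both generations. Or263 was at 2 ± 0.47 CPM in F2 diploids (n = 4) and 0.0978 ± 0.0629 CPM in F2 triploids (n = 5, log2 -4.27, SE 0.56, adjusted p = 3.8e-06). Or243 was at 11.3 ± 0.616 CPM in F14 diploids (n = 4) and 0.453 ± 0.32 CPM in F14 triploids (n = 4, log2 -4.64, SE 1.02, adjusted p = 0.00167). Or15 stood at 1.65 ± 0.281 against 0.067 ± 0.0555 CPM at F14 (log2 -4.54, SE 0.74, adjusted p = 0.000124). Or246 fell at F2 (log2 -5.11, SE 1.04, adjusted p = 0.00128) and F14 (log2 -3.67, SE 0.95, adjusted p = 0.00683). Or146 fell likewise (log2 -3.88, SE 0.92, adjusted p = 0.00368 at F2 and log2 -3.51, SE 0.93, adjusted p = 0.00757 at F14). Of 162 tested receptors, 113 were lower and 49 not called at F2 (135 lower when adjusted over the list alone). Their median was -3.14 (camera adjusted p = 1.91e-39, adjusted p = 0.248 with an estimated correlation). At F14 123 were lower and 39 uncalled (135 lower over the list alone). Their median was -2.92 (camera adjusted p = 9.48e-41, adjusted p = 0.248 with an estimated correlation). Without C62 81 were lower.

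Or1, the co-receptor that the other receptors need, moved with the list. It spanned 2.53 to 40.4 CPM in F2 triploid heads and 108 to 161 CPM in F2 diploid heads, and 3.17 to 79.1 against 329 to 377 CPM at F14. With log2 Or1 as a covariate, 7 receptors at F2 and 8 at F14 were still called lower. The calls of Or243, Or15, Or246 and Or146 ended, but Or1 itself separates the ploidies.

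**Figure D2:**
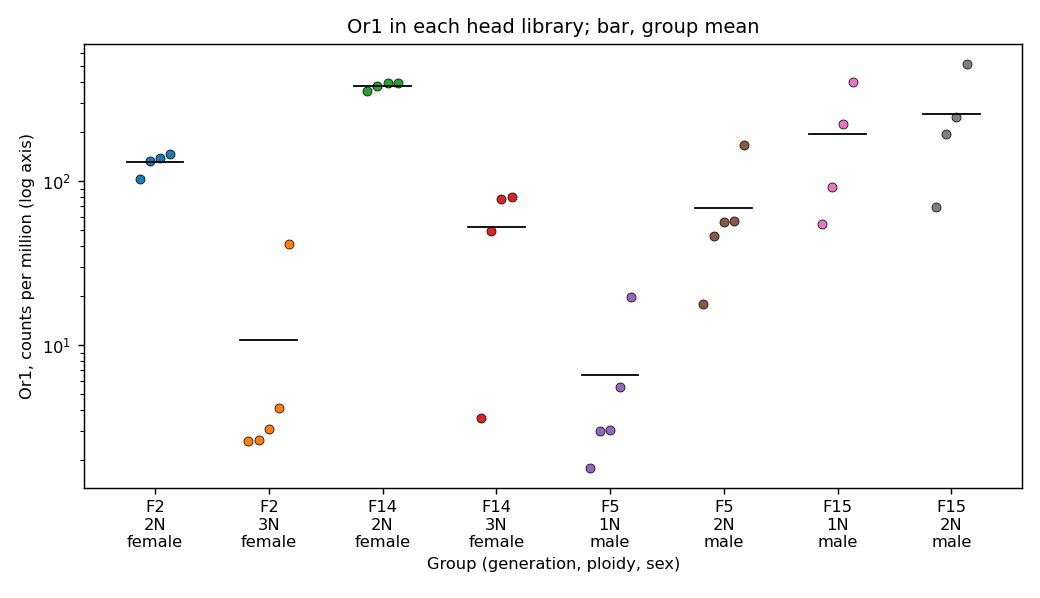
Points are Or1 levels (CPM of the library total, log axis) of single head libraries by group and bars are group means. Triploid females reach at most 79.4 CPM, and diploid females start at 102 CPM.

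Enzymes of detoxification were lower in triploid heads of F14 (n = 4 and 4). Glutathione S-transferases conjugate glutathione to foreign and oxidised compounds. Of 16, 12 fell and 4 were uncalled at F14 (13 lower over the list alone). Their median was -1.40 (camera adjusted p = 9.2e-11, adjusted p = 0.248 with an estimated correlation). GstD1 was at 98 ± 20.2 CPM in triploids and 445 ± 62.3 CPM in diploids (log2 -2.18, SE 0.30, adjusted p = 9.29e-06). GstS2 stood at 3.51 ± 1.92 against 24.3 ± 2.26 CPM (log2 -2.80, SE 0.38, adjusted p = 9.71e-06) and GstT2 at 16.4 ± 7.11 against 96.1 ± 14.4 CPM (log2 -2.55, SE 0.44, adjusted p = 0.000166). Cytochrome P450 genes, which oxidise foreign compounds and hormones, fell in 27 of 38 cases with 11 uncalled (28 lower over the list alone). Their median was -2.23 (camera adjusted p = 4.56e-14, adjusted p = 0.248 with an estimated correlation). CYP9P3 was at 9.07 ± 4.54 against 61.7 ± 7.01 CPM (log2 -2.77, SE 0.42, adjusted p = 3.98e-05). CYP4AB6 was at 4.14 ± 3.26 against 41.4 ± 8.76 CPM (log2 -3.34, SE 0.54, adjusted p = 7.82e-05), and CYP4AB23 at 3.43 ± 1.55 against 20.5 ± 4.57 CPM (log2 -2.59, SE 0.41, adjusted p = 5.84e-05). Carboxylesterases fell in 6 of 11 cases with 5 uncalled (6 lower over the list alone). Their median was -2.21 (camera adjusted p = 0.000388, adjusted p = 0.505 with an estimated correlation). CCE-E11 was at 11.3 ± 6.63 against 105 ± 26.6 CPM (log2 -3.22, SE 0.44, adjusted p = 9.29e-06), and CCE-E10 fell too (log2 -3.68, SE 0.66, adjusted p = 0.000219). With the Or1 covariate 8 transferases, 7 P450 genes and 2 esterases were called. The 3 lists varied with the receptors within groups (r = 0.81). Without C62 18 P450 genes and 4 esterases (median -1.16) were called, and without C61 20 and 4 (-1.16).

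At F2 the detoxification lists had members on both sides. Of the transferases 1 was higher, 4 were lower and 11 uncalled (median -0.13, camera adjusted p = 0.192). Of the P450 genes 4 were lower and 34 uncalled, with a median of 0.05 while the mean and camera lay below 0 (adjusted p = 0.531). Of the esterases 1 was lower and 10 were uncalled (median -0.55, camera adjusted p = 0.171). GstD5 fell at F2 (log2 -3.27, SE 0.56, adjusted p = 0.000135) and F14 (log2 -3.01, SE 0.60, adjusted p = 0.000676). CYP4AB15 did the same (log2 -3.13, SE 0.70, adjusted p = 0.00221 and log2 -2.91, SE 0.75, adjusted p = 0.00575). With the Or1 covariate the F2 call of GstD5 and both calls of CYP4AB15 ended.

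Cuticle genes, the royal jelly-like gene Mrjpl8 and the pigmentation genes of the yellow family also differed. At F2 the cuticle protein gene CPR48 was at 28.4 ± 10.4 CPM in triploid heads (n = 5) and 2760 ± 618 CPM in diploid heads (n = 4, log2 -6.60, SE 1.29, adjusted p = 0.00066). Mrjpl8 was at 0.0628 ± 0.0689 against 18.2 ± 3.84 CPM (log2 -8.01, SE 0.95, adjusted p = 9.37e-07). At F14 CPR16 was at 54.5 ± 18.2 against 244 ± 21.9 CPM (n = 4 and 4, log2 -2.16, SE 0.29, adjusted p = 6.67e-06). CPR22 was at 3.43 ± 1.01 against 35.5 ± 3.4 CPM (log2 -3.36, SE 0.75, adjusted p = 0.00178). CPR1 rose at F2 (log2 2.63, SE 0.54, adjusted p = 0.00104), a call that ended with the Or1 covariate, and fell at F14 (log2 -2.83, SE 0.57, adjusted p = 0.000701). Tropomyosin (Tm1) was at 432 ± 46.3 CPM in F2 triploid heads and 1713 ± 214 CPM in F2 diploid heads (log2 -1.99, SE 0.59, adjusted p = 0.019), and the muscle gene Zasp66 at 40.2 ± 14.6 against 177 ± 40.8 CPM (log2 -2.13, SE 0.59, adjusted p = 0.0116). At F14 Tm1 was uncalled (659 ± 282 against 800 ± 158 CPM, log2 -0.28, adjusted p = 0.808). Of 34 cuticle genes, 2 rose, 8 fell and 24 were uncalled at F2 (the same over the list alone). Their median was -1.03 (camera adjusted p = 0.0382, adjusted p = 0.814 with an estimated correlation). At F14 9 fell and 25 were uncalled (9 over the list alone). Their median was -0.88 (camera adjusted p = 0.00178, adjusted p = 0.639 with an estimated correlation). Y-y (log2 -2.23, SE 0.46, adjusted p = 0.000814) and Y-f (log2 -1.39, SE 0.32, adjusted p = 0.00259) were among 3 of 8 yellow genes lower at F14, with 5 uncalled (3 over the list alone). Their median was -0.98 (camera adjusted p = 0.0347, adjusted p = 0.58 with an estimated correlation).

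Some single genes were higher in triploid heads. Pdf, the neuropeptide of circadian pacemaker neurons, was at 244 ± 37.7 CPM in F2 triploids (n = 5) and 102 ± 18.5 CPM in F2 diploids (n = 4, log2 1.26, SE 0.29, adjusted p = 0.00289). At F14 it was at 159 ± 56.4 against 69.9 ± 3.69 CPM (log2 1.18, SE 0.30, adjusted p = 0.00543). The acetylcholine receptor subunit nAChRa8 rose from 143 ± 14.2 to 229 ± 15.3 CPM at F2 (log2 0.67, SE 0.15, adjusted p = 0.0022). It rose from 106 ± 1.05 to 158 ± 10.5 CPM at F14 (log2 0.58, SE 0.16, adjusted p = 0.00828). The Or1 covariate ended every call named in this paragraph. Leaving out C62 ended those of Pdf (log2 0.91, SE 0.32, adjusted p = 0.0619) and nAChRa8 (log2 0.51, SE 0.17, adjusted p = 0.0524) at F14.

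Genes of dynein and dynactin, a motor of intracellular transport, had 3 of 10 members higher and 7 uncalled in F2 heads (6 over the list alone). Their median was 0.37 (camera adjusted p = 0.0156, adjusted p = 0.639 with an estimated correlation). Ion channel and synapse genes had 4 higher, 2 lower and 14 uncalled of 20 at F2 (median -0.26, camera adjusted p = 0.819). At F14 4 were higher and 16 uncalled (5 over the list alone, median 0.14, camera adjusted p = 0.187). The sex determination genes were not called. Dsx was at 164 ± 21.8 against 214 ± 14.7 CPM at F2 (log2 -0.38, SE 0.17, adjusted p = 0.104) and 172 ± 21 against 239 ± 10.9 CPM at F14 (log2 -0.48, SE 0.18, adjusted p = 0.0531). Tra was at log2 0.42 (SE 0.27, adjusted p = 0.283) and 0.57 (SE 0.28, adjusted p = 0.153). Fru was at -0.25 (SE 0.29, adjusted p = 0.579) and 0.24 (SE 0.31, adjusted p = 0.646).

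In all, edgeR called 2191 genes in F2 heads, 976 higher in triploids and 1215 lower (170 and 881 at least 2-fold). In F14 heads it called 2467, 1115 higher and 1352 lower (210 and 1074 at least 2-fold). Called at both generations were 253 higher, 470 lower and 53 opposite genes (92.3, 139 and 227 under independence). Fisher's exact test (adjusted p = 1.38e-55 higher, 1.01e-154 lower) treats genes as independent, so its p describes these libraries only. Called genes were neighbours on the chromosomes in 303 pairs at F2 (207 in permutations, ratio 1.46) and 477 at F14 (261, ratio 1.82). The permutation p = 1e-04 of each is the smallest possible. Without C21 and C22 the F2 count was 1362 and 1437, and 3659 with the compared groups alone. Without C62, C61 and C74 the F14 count was 1358, 1475 and 1620. With the Or1 covariate the counts were 403 and 471. On TPM 1133 were higher and 749 lower at F2. At F14 767 were higher and 1409 lower with RLE size factors, and 573 and 1394 without the low-count filter.

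The effect of ploidy in female heads differed between F14 and F2 for 736 genes (272 more positive at F14, 464 more negative). Mrjpl8 had a difference of 8.79 (SE 1.22, adjusted p = 0.000198) and CPR1 of -5.46 (SE 0.78, adjusted p = 0.000198). CYP6AQ4 (-4.77, SE 1.14, adjusted p = 0.0106), CCE-E11 (-2.88, SE 0.57, adjusted p = 0.00234) and GstT2 (-2.45, SE 0.59, adjusted p = 0.011) were more negative at F14. By list, 16 of 38 P450 genes were more negative and 22 uncalled (21 over the list alone). Their median was -1.90 (camera adjusted p = 5e-11, adjusted p = 0.529 with an estimated correlation). Of 16 transferases 6 were more negative and 10 uncalled (8 over the list alone). Their median was -1.22 (camera adjusted p = 2.7e-06, adjusted p = 0.529 with an estimated correlation). Odorant receptors had 2 more positive and 160 uncalled (median 0.14, camera adjusted p = 0.655). The split was 125 and 357 on TPM and 173 and 483 without the filter. The count fell to 454, 459, 459 and 490 without C61, C74, C21 and C22.

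Female abdomens were compared for the same question. Called serine proteases, peptidases of digestion and signalling, were lower at F2 (5 of 40) and higher at F14 (24 of 40). SP142 was at 4.17 ± 1.88 CPM in F2 triploids (n = 5) and 42.6 ± 29.6 CPM in F2 diploids (n = 4, log2 -3.35, SE 0.62, adjusted p = 0.00289). SP49 was at 674 ± 784 CPM in F14 triploids (n = 4) and 1.96 ± 1.35 CPM in F14 diploids (n = 4, log2 8.43, SE 1.46, adjusted p = 0.000571). SP7 was at 81.3 ± 86 against 0.494 ± 0.207 CPM at F14 (log2 7.36, SE 1.44, adjusted p = 0.00112). SP110 fell at F2 (log2 -1.91, SE 0.44, adjusted p = 0.0101) and rose at F14 (log2 2.47, SE 0.48, adjusted p = 0.00109), a call that ended with the compared groups alone. Of 40 serine proteases, 5 were lower and 35 uncalled at F2 (6 over the list alone). Their median was -1.45 (camera adjusted p = 0.00582, adjusted p = 0.639 with an estimated correlation). At F14 24 were higher and 16 uncalled (27 higher and 1 lower over the list alone). Their median was 2.83 (camera adjusted p = 3.86e-05, adjusted p = 0.58 with an estimated correlation). The summed serine proteases reached 7304 CPM in C66 and 5348 CPM in C67, both F14 triploids.

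**Figure D3:**
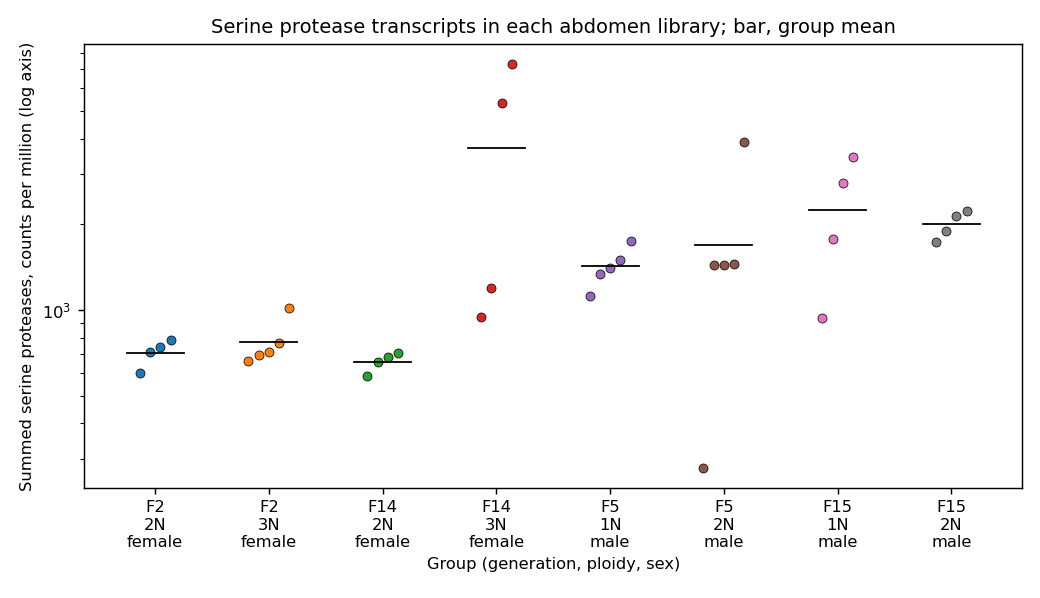
Points are summed serine protease transcripts (CPM, log axis) of single abdomen libraries by group and bars are group means. The F14 triploid libraries C66 and C67 stand at 7304 and 5348 CPM, and C68 and C69 at 1193 and 941.8 CPM.

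Called P450 genes and carboxylesterases of female abdomens were also lower at F2 and higher at F14. P450 genes had 9 lower and 31 uncalled of 40 at F2 (15 over the list alone). Their median was -1.49 (camera adjusted p = 2e-05, adjusted p = 0.58 with an estimated correlation). At F14 12 were higher and 28 uncalled (15 over the list alone, median 1.20, camera adjusted p = 0.0779). CYP9P5 fell at F2 from 4.17 ± 1.97 to 0.812 ± 0.478 CPM (log2 -2.35, SE 0.45, adjusted p = 0.00339), and CYP4AB9 from 46.9 ± 36.1 to 5.12 ± 2.41 CPM (log2 -3.19, SE 0.68, adjusted p = 0.00758). Carboxylesterases had 5 lower and 8 uncalled of 13 at F2 (6 over the list alone). Their median was -1.50 (camera adjusted p = 0.0112, adjusted p = 0.617 with an estimated correlation). At F14 7 were higher and 6 uncalled (8 over the list alone). Their median was 2.51 (camera adjusted p = 0.0313, adjusted p = 0.639 with an estimated correlation). Without C69 it was 1.64 with 4 called, and camera no longer passed (adjusted p = 0.124). CCE-A6 rose at F14 from 5.73 ± 1.8 to 59.6 ± 42.1 CPM (log2 3.37, SE 0.68, adjusted p = 0.00148), and CCE-A8 from 1.19 ± 0.435 to 20.1 ± 13.2 CPM (log2 4.06, SE 0.96, adjusted p = 0.0044).

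Cuticle and chitin genes had 6 lower and 30 uncalled of 36 in F2 abdomens (8 over the list alone). Their median was -1.24 (camera adjusted p = 0.00514, adjusted p = 0.691 with an estimated correlation). At F14 10 were higher and 26 uncalled (19 over the list alone). Their median was 2.75 (camera adjusted p = 0.00951, adjusted p = 0.742 with an estimated correlation). Without C69 it was 1.43 with 3 called, and camera no longer passed (adjusted p = 0.124). The chitinase gene Cht5 fell at F2 (log2 -3.42, SE 0.79, adjusted p = 0.0103) and rose from 3.75 ± 1.72 to 60.9 ± 56.3 CPM at F14 (log2 4.02, SE 0.87, adjusted p = 0.00245). Yellow genes had 3 lower and 6 uncalled of 9 at F2 (3 over the list alone). Their median was -1.21 (camera adjusted p = 0.0047, adjusted p = 0.505 with an estimated correlation). Dsx, the switch of sexual differentiation, fell at F2 from 168 ± 84.9 to 52.1 ± 18.9 CPM (log2 -1.69, SE 0.49, adjusted p = 0.0332). It rose at F14 from 56 ± 12.2 to 506 ± 429 CPM (log2 3.17, SE 0.56, adjusted p = 0.000571). Tra was at -0.73 at F2 (SE 0.30, adjusted p = 0.128) and rose at F14 (log2 1.53, SE 0.32, adjusted p = 0.00182). Fru was uncalled (log2 0.08, SE 0.24, adjusted p = 0.858 and log2 -0.27, SE 0.25, adjusted p = 0.45). On TPM the F2 calls of Cht5 and Dsx ended. Without C29 (-1.59), C28 (-1.41), C27 (-1.73), C37 (-1.62) or C36 (-1.55) the F2 call of Dsx ended too, and with the compared groups alone the F14 calls of Dsx and Tra ended.

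Genes of dividing cells lay on the other side of 0 in female abdomens. Cell cycle genes had 1 lower and 14 uncalled of 15 at F2. Their median was 0.65 (camera adjusted p = 0.00319, adjusted p = 0.58 with an estimated correlation). At F14 1 was lower and 14 were uncalled. Their median was -0.69 (camera adjusted p = 5.9e-05, adjusted p = 0.505 with an estimated correlation). DNA replication and repair had a median of 0.45 at F2 with all 16 uncalled by edgeR (camera adjusted p = 0.000715, adjusted p = 0.58 with an estimated correlation). At F14 1 was lower and 15 were uncalled. Their median was -0.45 (camera adjusted p = 0.000175, adjusted p = 0.58 with an estimated correlation). Cdk2, a kinase of entry into DNA synthesis, fell at F14 from 27.4 ± 4.88 to 10.3 ± 5.24 CPM (log2 -1.41, SE 0.39, adjusted p = 0.0115). That call ended without C69 (log2 -1.11, SE 0.37, adjusted p = 0.057), whose Tm1 level was 4864 CPM, and with the compared groups alone (adjusted p = 0.0791).

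The effect of ploidy in female abdomens differed between F14 and F2 for 4044 genes (3055 more positive at F14, 989 more negative). Cell cycle genes had 6 more negative, 1 more positive and 8 uncalled of 15. Their median was -1.38 (camera adjusted p = 8.94e-05, adjusted p = 0.529 with an estimated correlation). More positive were SP49 (12.53, SE 1.93, adjusted p = 4.13e-05), CYP9P5 (4.52, SE 0.64, adjusted p = 2.41e-05), CCE-A6 (5.77, SE 0.91, adjusted p = 5.03e-05) and Cht5 (7.43, SE 1.18, adjusted p = 5.13e-05). By list, 26 of 40 serine proteases were more positive and 14 uncalled (27 over the list alone). Their median was 5.13 (camera adjusted p = 4.49e-05, adjusted p = 0.692 with an estimated correlation). Of 40 P450 genes 24 were more positive and 16 uncalled (24 over the list alone). Their median was 2.89 (camera adjusted p = 0.000884, adjusted p = 0.692 with an estimated correlation). The count was 2687 without C69, and on TPM 1451 were more positive and 2031 more negative.

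Oxidative phosphorylation had 6 higher and 60 uncalled of 66 in F14 abdomens (2 over the list alone). Their median was 0.57 (camera adjusted p = 0.00582, adjusted p = 0.917 with an estimated correlation). The summed list reached 26480 CPM in C69 and at most 14480 CPM in the other triploids, and without C69 its median was 0.16 (camera adjusted p = 0.824). C69 had Tm1 at 4864 CPM, and the others of its group at most 1331 CPM. EdgeR called 922 genes in F2 abdomens, 64 higher in triploids and 858 lower (23 and 810 at least 2-fold; 125 on TPM, 1580 with DESeq2, 1508 with surrogate variables, 2254 with the compared groups alone and 1834 without the doubted libraries). In F14 abdomens it called 2447, 2229 higher and 218 lower (2091 and 43 at least 2-fold). Called at both generations were 4 higher and 0 lower genes (10 and 14 with DESeq2, 3028 and 4401 genes having an unadjusted p below 0.05 at F2 and F14). In opposite directions 584 were called (157 under independence, 969 with DESeq2, r = -0.56 across genes). Divisions of the F14 libraries that mix the groups called up to 3898 genes, so chance cannot be excluded for the F14 count. The F2 count fell to 227, 268, 460, 356 and 310 without C29, C28, C27, C37 and C36 and was 1773 without C30. The F14 count was 1037, 1414, 1481 and 1353 without C69, C79, C77 and C76, 5005 without C68, and 429 with the compared groups alone. At F14 2623 were higher and 723 lower with DESeq2, and 863 and 1863 on TPM, where the median was -0.09 in place of 0.169.

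**Figure D4:**
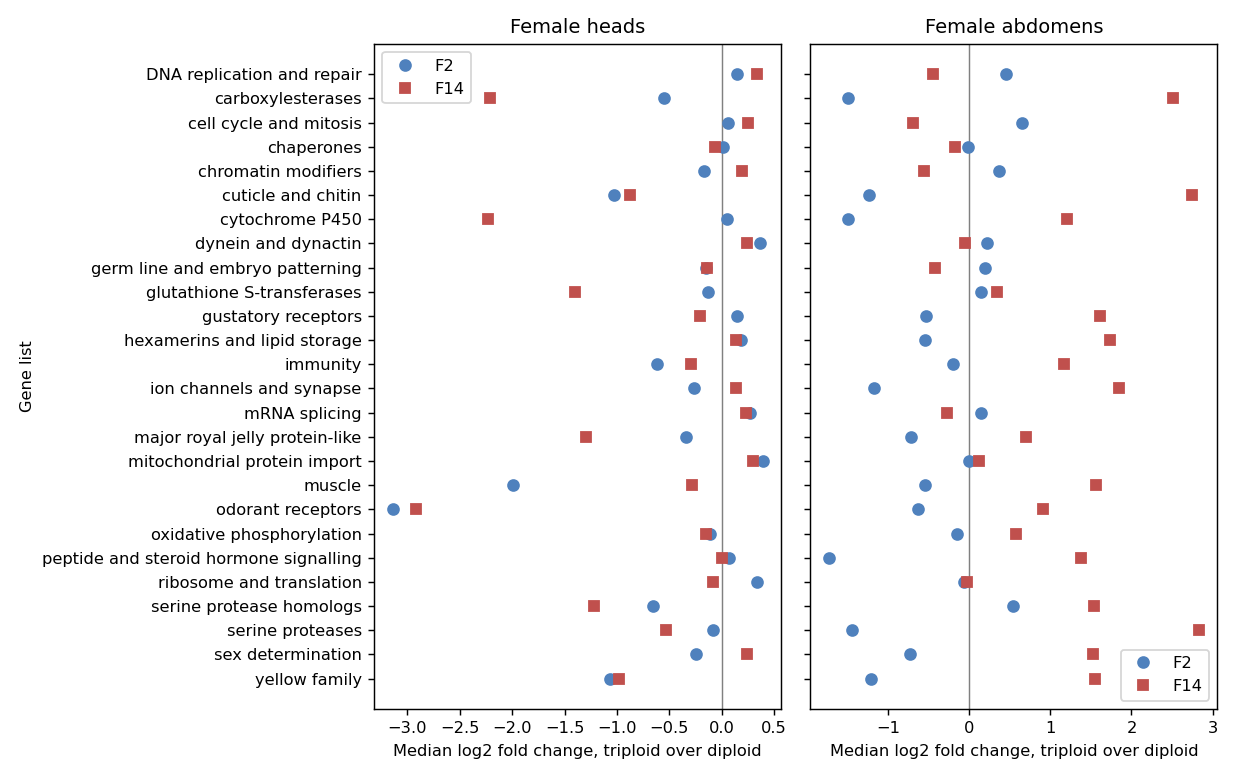
Symbols are the median log2 fold change, triploid over diploid, of the tested members of each gene list at F2 (circles) and F14 (squares), for heads and abdomens. Serine proteases in abdomens lie at -1.45 and 2.83, and odorant receptors in heads at -3.14 and -2.92.

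Heads of diploid and haploid males were compared for the same question. LOC100678896, chosen after its values were seen, rose in F5 diploids from 5.22 ± 0.517 to 15.6 ± 0.28 CPM (n = 5 and 5, log2 1.58, SE 0.12, adjusted p = 7.89e-10). In F15 diploids it rose from 5.17 ± 0.359 to 11.7 ± 2.49 CPM (n = 4 and 4, log2 1.18, SE 0.14, adjusted p = 1.21e-05). Diploid females stood at 16.6 ± 1.41 CPM (F2) and 16 ± 1.35 CPM (F14). LOC100680350, chosen in the same way, rose at F5 from 232 ± 14.9 to 421 ± 27 CPM (log2 0.86, SE 0.11, adjusted p = 2.02e-05). At F15 it rose from 220 ± 44.1 to 350 ± 32.7 CPM (log2 0.67, SE 0.12, adjusted p = 0.0112). With the compared groups alone both F15 calls ended (adjusted p = 0.606 and 0.803). That of LOC100680350 also ended without the 8 doubted libraries (0.44, adjusted p = 0.394) and without C94 (0.65), C92 (0.63), C82 (0.60) or C81 (0.59), and DESeq2 gave LOC100678896 no adjusted p. Odorant receptors were higher in F5 diploids for 13 of 162, with 149 uncalled (82 over the list alone). That count was 1 without C43, C55B, C52 or C51, 2 without C54 and 4 without C45. Without C41, C42 and C53 it was 21, 34 and 42. It was 0 with the Or1 covariate (median -0.17) and 0 of 28 with the compared groups alone (median 0.5). Over all 162 the median was 2.09 (camera adjusted p = 1.97e-40, adjusted p = 0.248 with an estimated correlation). Or1 spanned 20 to 159 CPM in these diploids and 1.65 to 21.2 CPM in the haploids. GstD5 rose at F5 from 1.76 ± 1.29 to 12.5 ± 8.26 CPM (log2 2.85, SE 0.56, adjusted p = 0.0189). Its call ended without C43 (2.52), C55B (2.68), C54 (2.73), C52 (2.85) or C51 (2.74), with the compared groups alone (2.86), and with the Or1 covariate (0.78). Dsx was at -0.03 (SE 0.16, adjusted p = 0.978) at F5 and 0.02 (SE 0.18, adjusted p = 0.972) at F15. Tra was at -0.58 (SE 0.25, adjusted p = 0.427) and 0.27 (SE 0.28, adjusted p = 0.701), and Fru at 0.29 (SE 0.28, adjusted p = 0.778) and 0.57 (SE 0.31, adjusted p = 0.431).

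At F15 no gene named by the rule passed in male heads. Ion channel and synapse genes had 2 higher over the list alone. Their median was 0.49 (camera adjusted p = 2.8e-05, adjusted p = 0.353 with an estimated correlation). The dopamine receptor gene Dop2 was at 29.2 ± 3.71 against 19.1 ± 1.41 CPM (log2 0.61, SE 0.18, adjusted p = 0.232). Cuticle genes had 2 lower over the list alone. Their median was -0.88 (camera adjusted p = 2.64e-05, adjusted p = 0.58 with an estimated correlation). Serine proteases also had 2 lower over the list alone. Their median was -0.73 (camera adjusted p = 0.01, adjusted p = 0.58 with an estimated correlation). Summed cuticle transcripts were at 19640 and 26210 CPM in the haploids C81 and C82, 14530 and 9525 CPM in the diploids C91 and C92, and 953 CPM in the diploid C93.

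EdgeR called 50 genes in F5 male heads, 38 higher in diploids and 12 lower (37 and 7 at least 2-fold, 1215 at unadjusted p below 0.05). At F15 it called 3, all of them higher (2 at least 2-fold, 1549 at unadjusted p below 0.05). Without the 8 doubted libraries (C83 and C84 against C93 and C94 left) 1 was higher and 8 lower, and without C91 41 and 274. DESeq2 called 178 and 50. LOC100678896 and LOC100680350, whose F15 calls ended with the compared groups alone, were the 2 genes higher at both generations (0.00967 under independence, Fisher's exact test, adjusted p = 6.06e-05). The difference of effects was called for 1 gene, LOC100113772 (-3.74, SE 0.60, adjusted p = 0.00884), named after its value was seen. That call ended without C84 (-3.34, adjusted p = 0.0583), without the 8 doubted libraries (-3.80, adjusted p = 0.054) and with the compared groups alone (-3.73, adjusted p = 0.324). Divisions that mix the groups called up to 1277 genes at F5 and 2117 at F15. This points to a structure of the samples other than ploidy, and chance cannot be excluded for either count. Left-out libraries moved the F5 count to between 7 (C55B) and 217 (C42) and the F15 count to between 2 (C94) and 315 (C91).

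Abdomens of diploid and haploid males gave few calls at F5 and many at F15. LOC100680350, chosen after its values were seen, rose in F5 diploids from 160 ± 18.4 to 460 ± 190 CPM (n = 5 and 5, log2 1.53, SE 0.20, adjusted p = 0.000127), a call that ended with the compared groups alone (adjusted p = 0.516). In F15 diploids it rose from 190 ± 34.3 to 448 ± 58.9 CPM (n = 4 and 4, log2 1.24, SE 0.22, adjusted p = 0.000262). The respiratory chain genes Cox6c (0.197 ± 0.23 against 12.5 ± 7.9 CPM, log2 -6, SE 1.41, adjusted p = 0.00571) and Cox7a1 (0.704 ± 0.671 against 40 ± 25.1 CPM, log2 -5.82, SE 1.17, adjusted p = 0.0012) fell in F15 diploids. The cuticle genes CPR53 (2.77 ± 0.472 against 29.2 ± 22.8 CPM, log2 -3.40, SE 0.61, adjusted p = 0.000313) and TWDL2 (0.566 ± 0.758 against 96 ± 152 CPM, log2 -7.41, SE 1.34, adjusted p = 0.000345) fell with them. GstT1 rose from 30.1 ± 8.89 to 165 ± 15.3 CPM (log2 2.46, SE 0.47, adjusted p = 0.000559). CYP4AB21 fell from 179 ± 76.2 to 17 ± 14.8 CPM (log2 -3.40, SE 0.85, adjusted p = 0.0054). Without C87 TWDL2 was at -5.21 (SE 1.21, adjusted p = 0.00538). Tropomyosin (Tm1) reached 4201 and 5072 CPM in the F15 haploid abdomens C86 and C87 and at most 1210 CPM in F15 diploids. Oxidative phosphorylation had 4 lower and 62 uncalled of 66 (median -0.30, camera adjusted p = 0.101).

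By list, F15 male abdomens had 1 higher, 15 lower and 20 uncalled of 36 cuticle genes (1 and 19 over the list alone). Their median was -2.24 (camera adjusted p = 0.0215, adjusted p = 0.778 with an estimated correlation). P450 genes had 5 higher, 3 lower and 32 uncalled of 40 (9 and 3 over the list alone). Their median was 0.93 (camera adjusted p = 0.000212, adjusted p = 0.626 with an estimated correlation). In F5 abdomens oxidative phosphorylation had a median of 0.37 with all 66 uncalled by edgeR (camera adjusted p = 2.64e-05, adjusted p = 0.814 with an estimated correlation). That rested on C46, whose sum was 33650 CPM against at most 17320 CPM in the other F5 males, since without it the median was 0.01 (camera adjusted p = 0.65). Dsx was at -0.40 (SE 0.46, adjusted p = 0.672) at F5 and 0.72 (SE 0.51, adjusted p = 0.391) at F15. Tra was at -0.31 (SE 0.28, adjusted p = 0.571) and 0.63 (SE 0.32, adjusted p = 0.19), and Fru at 0.35 (SE 0.22, adjusted p = 0.399) and 0.07 (SE 0.25, adjusted p = 0.903).

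EdgeR called 47 genes in F5 male abdomens, 31 higher in diploids and 16 lower (18 and 10 at least 2-fold). At F15 it called 2149, 635 higher and 1514 lower (340 and 1208 at least 2-fold), and without the 8 doubted libraries 1186. Called at both were 4 higher genes (1.6 under independence, Fisher's exact p = 0.0733) and 6 lower (1.97, adjusted p = 0.0122), all with LOC symbols. The effect differed between F15 and F5 for 514 genes (126 more positive at F15, 388 more negative). The cuticle genes apd-3 (-15.67, SE 2.84, adjusted p = 0.00203) and CPLCP2 (-10.76, SE 2.20, adjusted p = 0.00516) were among them. Their F15 haploid levels were 27000 and 997 (C87), 2520 and 234 (C86), 293 and 175 (C88) and 1.22 and 0.695 CPM (C89). Without the 8 doubted libraries, which leaves C88 and C89, the differences were -6.94 and -5.52 (adjusted p = 0.0215 and 0.0435). These calls rest on C88, since C89 lay at the F15 diploid level. Cuticle genes as a list had 8 more negative and 28 uncalled of 36 (12 over the list alone). Their median was -1.99 (camera adjusted p = 0.00689, adjusted p = 0.702 with an estimated correlation). The opsin gene Lop1 was at 3091 CPM in the F5 diploid abdomen C46 and at most 0.323 CPM in the others of its group. The difference of effects of Lop1 was -11.34 (SE 2.97) with C46 and 0.09 (SE 1.54) without it.

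Divisions of the male abdomens that mix the groups called up to 661 genes at F5 and 1665 for the difference of effects, so chance cannot be excluded for the counts of 47 and 514. Left-out libraries moved the F5 count to between 2 (C60) and 864 (C48) and the F15 count to 1423 (C87). They moved the count of differing effects to between 206 (C98) and 933 (C49). At F5 42 were higher and 12 lower with RLE size factors, and 12 and 524 on TPM. The difference had 180 more positive and 195 more negative on TPM.

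Generations were compared within each sex to ask what separates early from late collections of the line. In female heads genes of oxidative phosphorylation fell from F2 to F14. Ndufa13 of complex I went from 463 ± 69.3 to 179 ± 29.7 CPM (n = 9 and 8, log2 -1.39, SE 0.16, adjusted p = 4.35e-07). Uqcr10 of complex III went from 255 ± 54.8 to 76.6 ± 13.9 CPM (log2 -1.73, SE 0.24, adjusted p = 5e-06). Cox6a1 of complex IV went from 641 ± 117 to 211 ± 35 CPM (log2 -1.61, SE 0.22, adjusted p = 4.41e-06), and Atp5i of ATP synthase from 488 ± 101 to 126 ± 21 CPM (log2 -1.97, SE 0.29, adjusted p = 7.35e-06). Of 64 members 57 fell, 1 rose and 6 were uncalled (59 and 1 over the list alone). Their median was -1.09 (camera adjusted p = 1.12e-20, adjusted p = 0.692 with an estimated correlation). Rpl41, of the large ribosomal subunit, fell from 356 ± 150 to 86.9 ± 26.8 CPM (log2 -2.03, SE 0.25, adjusted p = 8.7e-07). Dynein and dynactin had 9 lower and 1 higher of 10 (9 and 1 over the list alone). Their median was -0.50 (camera adjusted p = 0.00689, adjusted p = 0.692 with an estimated correlation). Odorant receptors had 67 higher and 95 uncalled of 162 (63 over the list alone). Their median was 1.24 (camera adjusted p = 3.74e-08, adjusted p = 0.692 with an estimated correlation).

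In male heads odorant receptors also rose, with 114 higher, 1 lower and 47 uncalled of 162 (125 and 1 over the list alone). Their median was 2.30 (camera adjusted p = 8.8e-28, adjusted p = 0.529 with an estimated correlation). In diploids alone 13 were higher (median 1.13) and in haploids alone 107 (median 3.24). Or26 went from 0.697 ± 0.583 to 3.45 ± 1.88 CPM (n = 10 and 8, log2 2.73, SE 0.40, adjusted p = 8.71e-06), a call that ended with the Or1 covariate. Cuticle genes rose in 21 of 34 cases, with 2 lower and 11 uncalled (22 and 2 over the list alone). Their median was 1.78 (camera adjusted p = 0.000108, adjusted p = 0.692 with an estimated correlation). CPR53 went from 1.92 ± 1.32 to 132 ± 146 CPM (log2 5.95, SE 0.78, adjusted p = 2e-06), and Cpap3-a1 from 2.18 ± 1.34 to 22.7 ± 19.4 CPM (log2 3.13, SE 0.36, adjusted p = 3.28e-07). CPR49 fell (log2 -1.09, SE 0.15, adjusted p = 5.53e-06), and so did CYP9AH6 (log2 -1.33, SE 0.14, adjusted p = 7.53e-08). Tm1 reached 4709, 6249, 6159 and 3281 CPM in the F15 heads C81, C82, C91 and C92.

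In female abdomens, over both ploidies, 14 of 40 serine proteases were higher at F14 and 26 uncalled (18 higher and 2 lower over the list alone). Their median was 1.64 (camera adjusted p = 1.24e-05, adjusted p = 0.671 with an estimated correlation). In triploids alone 29 were higher and 1 lower with a median of 4.72, and in diploids alone 0 were called with a median of -0.34. C66 and C67 had the highest sums. SP49 (log2 6.41, SE 0.97, adjusted p = 0.000165) rose in triploids (12.68, adjusted p = 2.97e-06) and not in diploids (0.15, adjusted p = 0.984). SP137 (log2 3.92, SE 0.81, adjusted p = 0.00294) did likewise (7.32, adjusted p = 5.99e-05 and 0.53, adjusted p = 0.884). Ndufab1 fell from 355 ± 32.6 to 206 ± 30.5 CPM (log2 -0.79, SE 0.15, adjusted p = 0.00141). In male abdomens oxidative phosphorylation had 1 higher, 16 lower and 49 uncalled of 66 (1 and 21 over the list alone), with 22 lower in diploids alone and 1 in haploids alone. Their median was -0.34 (camera adjusted p = 4.73e-05, adjusted p = 0.776 with an estimated correlation). Without C46, at 33650 CPM of the list, 1 was higher and 9 were lower, and the median was -0.19 (camera adjusted p = 0.0248). Atp5i fell (log2 -1.20, SE 0.27, adjusted p = 0.00252) and Cox15 rose (log2 0.64, SE 0.16, adjusted p = 0.00829), calls that held without C46 (log2 -0.95, adjusted p = 0.00383 and log2 0.65, adjusted p = 0.00714).

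Counts for generation were 5476 in female heads (2664 higher late, 2812 lower), 4061 in male heads (2093 and 1968), 1383 in female abdomens (1062 and 321; 5195 in triploids alone and 21 in diploids alone) and 2163 in male abdomens (966 and 1197). On TPM these splits became 5596 and 596, 1797 and 810, 801 and 104, and 1914 and 433, so the direction of the bulk of small changes depends on the scaling. Mixed divisions of female abdomens called up to 4209 genes, and chance cannot be excluded for that count. It was 813, 859 and 2902 without C30, C66 and C68. Male heads had 2345 calls without the 8 doubted libraries, 2382 with the Or1 covariate and 2537 with the compared groups alone. Male abdomens had 1182 with the compared groups alone.

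Sexes were compared at the same ploidy by setting diploid males (n = 9) against diploid females (n = 8). In abdomens the germ plasm gene oskar was at 1.67 ± 0.528 CPM in males and 656 ± 57.1 CPM in females (log2 -8.61, SE 0.23, adjusted p = 8.05e-23). Nanos, of the same pathway, was at 0.0424 ± 0.0876 against 80.2 ± 18.8 CPM (log2 -10.63, SE 0.53, adjusted p = 1e-15). The mitotic genes cycB (2.08 ± 2.46 against 941 ± 304 CPM, log2 -9.06, SE 0.69, adjusted p = 5.49e-13) and Cdk1 (1.28 ± 0.886 against 232 ± 55.8 CPM, log2 -7.72, SE 0.38, adjusted p = 3.79e-17) were lower in males. The splicing gene Sf3b3 was lower too (log2 -2.06, SE 0.16, adjusted p = 1.56e-12). All 15 cell cycle genes were lower. Their median was -3.46 (camera adjusted p = 3.73e-07, adjusted p = 0.529 with an estimated correlation). Of 10 germ line and patterning genes 9 were lower and 1 higher. Their median was -4.49 (camera adjusted p = 0.000347, adjusted p = 0.529 with an estimated correlation). Of 16 DNA replication genes 14 were lower. Their median was -2.15 (camera adjusted p = 0.00017, adjusted p = 0.692 with an estimated correlation). Of 11 splicing genes 10 were lower. Their median was -1.40 (camera adjusted p = 0.00224, adjusted p = 0.529 with an estimated correlation). Of 12 ribosome genes 11 were lower. Their median was -0.97 (camera adjusted p = 0.00767, adjusted p = 0.692 with an estimated correlation). Above the threshold of camera were chaperones (5 of 6 lower, median -1.24, adjusted p = 0.0765), chromatin modifiers (5 lower and 1 higher of 6, median -2.04, adjusted p = 0.0792) and mitochondrial protein import (3 lower and 1 higher of 5, median -0.34, adjusted p = 0.597).

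Higher in male abdomens was CYP4AB14 (1680 ± 617 against 1.93 ± 2.15 CPM, log2 10.32, SE 0.87, adjusted p = 6.42e-12). CYP6CK8 was at 202 ± 106 against 0.522 ± 0.422 CPM (log2 8.62, SE 0.66, adjusted p = 5.92e-13). The synaptotagmin gene Syt1 was at 262 ± 393 against 14.2 ± 7.1 CPM (log2 4.08, SE 0.52, adjusted p = 2.75e-08), and at 3.22 (SE 0.34, adjusted p = 5.58e-10) without the male abdomen C46, which carries head transcripts. By list, P450 genes had 35 higher and 3 lower of 40. Their median was 4.46 (camera adjusted p = 0.000108, adjusted p = 0.692 with an estimated correlation). Ion channels had 19 higher and 1 lower of 20. Their median was 3.87 (camera adjusted p = 0.0435, adjusted p = 0.776 with an estimated correlation). Without C46 18 were higher with a median of 2.76 (camera adjusted p = 0.0431), and without C69 camera no longer passed (adjusted p = 0.0547). Cuticle genes had 26 higher and 2 lower of 36. Their median was 3.33 (camera adjusted p = 0.0434, adjusted p = 0.776 with an estimated correlation), and 3.21 without C46, where camera no longer passed (adjusted p = 0.06). Yellow genes had 8 higher and 1 lower of 9. Their median was 4.61 (camera adjusted p = 0.0341, adjusted p = 0.692 with an estimated correlation). Also above it were gustatory receptors (11 higher of 12, median 3.37, adjusted p = 0.106) and immunity (6 higher of 7, median 2.21, adjusted p = 0.304). So were royal jelly-like genes (5 higher and 1 lower of 7, median 3.34, adjusted p = 0.201) and serine protease homologs (3 higher and 1 lower of 6, median 1.01, adjusted p = 0.877). Members not counted here were uncalled, and counts over each list alone were the same for every list of the abdominal comparison.

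In heads Tra, whose female form directs female development in this wasp, was at 74.5 ± 28.3 CPM in males (n = 9) and 426 ± 122 CPM in females (n = 8, log2 -2.50, SE 0.20, adjusted p = 5.85e-10). Fru was at 106 ± 45.4 against 244 ± 53.3 CPM (log2 -1.18, SE 0.22, adjusted p = 0.000472) and Dsx at 136 ± 31.3 against 226 ± 17.8 CPM (log2 -0.75, SE 0.12, adjusted p = 0.000111). In abdomens Dsx was higher in males (453 ± 150 against 112 ± 82.2 CPM, log2 2.23, SE 0.37, adjusted p = 3.12e-06). Tra was lower there (log2 -0.69, SE 0.22, adjusted p = 0.00424) and Fru uncalled (log2 -0.16, SE 0.17, adjusted p = 0.391). CYP6CK8 (log2 6.36, SE 0.62, adjusted p = 2.12e-08) and CYP6CK11 (log2 7.43, SE 0.81, adjusted p = 3.46e-07) were higher in male heads, and CCE-E10 lower (log2 -2.05, SE 0.41, adjusted p = 0.00128). Odorant receptors of heads had 2 higher, 37 lower and 123 uncalled of 162 (3 and 53 over the list alone). Their median was -0.83 (camera adjusted p = 1.08e-21, adjusted p = 0.531 with an estimated correlation). Or278 (log2 -4.05, SE 0.64, adjusted p = 7.54e-05) and Or281 (log2 -4.70, SE 0.64, adjusted p = 8.19e-06) were lower in males. Cuticle genes had 12 higher and 22 uncalled of 34 (16 over the list alone). Their median was 1.12 (camera adjusted p = 0.000481, adjusted p = 0.692 with an estimated correlation). EdgeR called 1061 genes in heads (678 higher in males, 383 lower) and 10386 in abdomens (6095 and 4291). The head count was 631 without the 8 doubted libraries. On TPM the splits were 176 and 761 in heads and 4666 and 5153 in abdomens, where the median moved from 0.613 to 0.049.

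Tissues were compared to place these groups of genes. In females (n = 17 and 17) Lop1 was at 4220 ± 2240 CPM in heads and 0.0697 ± 0.227 CPM in abdomens (log2 17.16, SE 0.41, adjusted p = 4.53e-24). Pdf was at 164 ± 84.8 against 0.052 ± 0.0688 CPM (log2 11.83, SE 0.26, adjusted p = 7.25e-25), and Or1 at 148 ± 159 against 0.924 ± 1.33 CPM (log2 6.65, SE 0.53, adjusted p = 6.52e-13). The histamine-gated channel gene HisCl1 (log2 9.05, SE 0.28, adjusted p = 2.25e-23) and nAChRa8 (log2 5.06, SE 0.11, adjusted p = 1.26e-26) were higher in heads. Abdomens were higher for cycB (0.498 ± 0.22 against 1020 ± 468 CPM, log2 -10.87, SE 0.33, adjusted p = 1.87e-23) and oskar (log2 -6.93, SE 0.12, adjusted p = 9.53e-29). The ribosomal gene Rpl6 was at 258 ± 81.9 against 1370 ± 134 CPM (log2 -2.49, SE 0.07, adjusted p = 1.01e-23). All 20 ion channel genes were higher in female heads. Their median was 6.71 (camera adjusted p = 5.8e-08, adjusted p = 0.529 with an estimated correlation). All 5 hormone signalling genes were higher too. Their median was 7.23 (camera adjusted p = 0.0111, adjusted p = 0.529 with an estimated correlation). Of 149 odorant receptors 125 were higher and 3 lower. Their median was 4.19 (camera adjusted p = 0.0122, adjusted p = 0.806 with an estimated correlation).

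In males (n = 18 and 18) oxidative phosphorylation had 62 higher in heads, 3 lower and 1 uncalled of 66 (63 and 3 over the list alone). Their median was 0.68 (camera adjusted p = 0.00136, adjusted p = 0.846 with an estimated correlation). Ndufv1 was at 661 ± 114 against 326 ± 102 CPM (log2 1.03, SE 0.10, adjusted p = 1.58e-10). Abdomens were higher for CYP4G44 (6.46 ± 5.79 against 786 ± 400 CPM, log2 -6.93, SE 0.56, adjusted p = 7.44e-12). GstS2 was at 9.12 ± 3.9 against 173 ± 69.3 CPM (log2 -4.26, SE 0.27, adjusted p = 9.34e-14) and SP19 at 1.81 ± 0.976 against 201 ± 112 CPM (log2 -6.69, SE 0.44, adjusted p = 1.33e-13). P450 genes were lower in heads for 31 of 39 and higher for 6. Their median was -1.79 (camera adjusted p = 0.000108, adjusted p = 0.692 with an estimated correlation). Serine proteases were lower in heads for 23 of 34 and higher for 2. Their median was -2.26 (camera adjusted p = 0.00531, adjusted p = 0.692 with an estimated correlation). EdgeR called 10768 genes in females (5753 higher in heads, 5015 lower) and 9321 in males (4621 and 4700). On TPM the male split was 5729 and 3535 (median 0.218 in place of -0.016).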

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

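The tests of low receptor counts, of triploidy itself, of the ovary share and of an effect that differs between generations were chosen only after the result was seen.

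Odorant receptors were lower in triploid female heads at both generations; in F5 males 13 of 162 were called higher in diploids (1 without C43, C51, C52 or C55B) and Or1 was not called (log2 3.34, SE 0.82, adjusted p = 0.0572). Low counts alone are argued against by Or1, an abundant receptor gene at log2 -3.74 at F2 (SE 0.85, adjusted p = 0.00272) and -2.83 at F14 (SE 0.89, adjusted p = 0.0219), where 15.5% and 14.3% of the 161 other receptors lay within 2 SE of 0. Less antennal RNA in those heads stays open, since 68.3% of the other receptors at F2 lay within 2 SE of the Or1 change (72% at F14, 58.4% at F5), which a common factor could give. Triploidy itself also stays open: Or1 reached at most 21.2 CPM in F5 haploid male heads, so low levels also occur without an additional chromosome set. How much antenna each head library held is not given in the sources used here, and the 2 readings cannot be told apart.

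The F5 diploid male abdomen C46 carries head transcripts, with Lop1 at 3091 CPM (at most 0.323 CPM in the other 4 of its group; mean of F5 diploid heads 3310 CPM) and CPR48 at 14025 CPM (heads 12569 CPM). Head RNA mixed into an abdomen library would give shares of head-specific and abdomen-specific genes that sum to about 1, and the sum of 0.763 does not exclude it, but the abdomen-specific genes would then keep the remaining share and their upper quartile of 0.00324 argues against it. A swap with a head library of the same group is argued against by the highest share of abdomen-specific genes in those heads, 0.0052. A head library carrying the wrong label had its predicted value, a median share of 0.000757 for 200 abdomen-specific genes beside 0.762 for 40 head-specific genes, so it is the likely source. No biological explanation was tested.

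In female abdomens the effect of ploidy ran in opposite directions at F2 and F14. A few genes taking most of the counts is argued against, since the 10 most abundant genes held 1.4 points more of the counts in F14 triploids than in F14 diploids (6.78%, SD 2.64, against 5.38%, SD 0.121). A different share of ovary RNA could give such a turn: of 933 genes at least 4-fold higher in male abdomens, 62.4% lay within 2 SE of their median at F14 (1.23; -0.92 at F2), and the 1555 genes higher in female abdomens moved the other way (-0.49 at F14, 0.36 at F2). An effect of ploidy that differs between generations also stays open, with 1037 genes called at F14 without C69. The design holds no measure of ovary size, so these cannot be told apart.

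Divisions of the same libraries that mix the compared groups were counted for every contrast, the real division included, so the lowest is 1. For ploidy in female heads chance can be excluded (F2, 2191 genes, 1 of 40 divisions as large, highest other 476; F14, 2467, 1 of 35, highest other 2), as it can for F2 female abdomens (922, 1 of 40, 866) and F15 male abdomens (2149, or 1186 without the doubted libraries, 1 of 35, 968). Chance cannot be excluded for F14 female abdomens (2447, 5 of 35, 3898), F5 male heads (50, 3 of 40, 1277), F15 male heads (3, 12 of 35, 2117) or F5 male abdomens (47, 14 of 40, 661). In the last 3 some divisions called many times the real count, which points to a structure other than ploidy. Chance can be excluded for the difference of effects in female heads (736, 1 of 40, 0) and female abdomens (4044, 1 of 40, 2104), and cannot for male heads (1, 11 of 40, 1229) and male abdomens (514, 6 of 40, 1665), where the same structure is seen. For generation it can be excluded in female heads (5476, 1 of 40, 2647), male heads (4061, 1 of 40, 2677) and male abdomens (2163, 1 of 40, 544) and cannot in female abdomens (1383, 3 of 40, 4209), where a division called several times the real count and points to a structure of the samples. For sex (1061 in heads, 1 of 40, 216; 10386 in abdomens, 1 of 40, 8970) and tissue (10768 in females, 1 of 40, 74; 9321 in males, 1 of 40, 2590) it can be excluded.

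A library was taken to stand apart when a Dixon test set it off from the rest of its group; 19 of 155 such tests did so, where chance gives about 5%. Genes with at least 10 counts numbered 11147 in the F15 diploid male abdomen C99 (next 10746) and 9613 in the F2 diploid female abdomen C30 (next 10297). The 10 most abundant genes held 10.7% of the counts in the F14 triploid abdomen C69 (next 5.83%), which also had the highest tropomyosin (Tm1, 4864 CPM against 1331 CPM), oxidative phosphorylation (26480 against 14480 CPM) and cuticle sums (2869 against 428 CPM) of its group. Or1 was at 41.2 CPM in the F2 triploid head C34 (next 4.13 CPM), 19.6 CPM in the F5 haploid head C53 (next 5.55 CPM) and 166 CPM in the F5 diploid head C43 (next 57 CPM). Summed odorant receptors were at 116 CPM in C34 (next 36.2 CPM), 376 CPM in C43 (next 158 CPM) and 38.8 CPM in the F2 diploid abdomen C27 (next 23.3 CPM). C46 stood apart with Or1 at 20.6 CPM (next 1.98 CPM), Lop1 at 3091 CPM (next 0.323 CPM), CPR48 at 14020 CPM (next 0), an oxidative phosphorylation sum of 33650 CPM (next 16290 CPM) and a cuticle sum of 15790 CPM (next 3733 CPM). Summed serine proteases were at 362 CPM in the F15 diploid head C93 (next 288 CPM) and 1018 CPM in the F2 triploid abdomen C39 (next 763 CPM).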

How the results depend on the processing

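The fit without 8 doubted libraries, the fit with log2 Or1 as a covariate, the list tests without C46 or C69, generation in each ploidy alone and the joining of libraries by code were chosen only after the result was seen. No source joins a head to an abdomen or a diploid to a triploid. Joining heads and abdomens of a group whose codes lie 5 apart gave 10653 calls for tissue in females and 9120 in males (10768 and 9321 unpaired). Over 34 such pairs, deviations from group means had r = 0.355 for Tm1 (permutation p = 0.0355) and a mean r of 0.0485 over 11281 genes (permutation p = 0.146), so the joining is not established. Generation called 1930 genes in F2 and F14 diploid female heads, 1198 and 2697 in diploid and haploid male heads, 5195 and 21 in triploid and diploid female abdomens and 1435 in diploid male abdomens. RLE size factors moved no count by more than 1.5 times. Where the reason for a shift is not named, the cause was not tested.

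With DESeq2 the calls were 178 for ploidy in F5 male heads (edgeR 50), 50 in F15 male heads (3), 1580 in F2 female abdomens (922) and 725 in F5 male abdomens (47), and for the difference of effects 30 in male heads (1) and 1026 in male abdomens (514). Genes called by DESeq2 at both generations were 1 higher in male heads, 10 higher, 14 lower and 969 opposite in female abdomens, and 54 higher, 73 lower and 36 opposite in male abdomens; the cause was not tested.

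With the compared groups alone in the fit the calls were 3659 in F2 female heads, 2254 and 429 in F2 and F14 female abdomens, 2 and 0 in F5 and F15 male heads and 0 in F5 male abdomens. In F15 male heads and F5 male abdomens 1549 and 2384 genes had an unadjusted p below 0.05 in edgeR with all groups, and DESeq2 called 50 and 725. Differences of effects numbered 2125 (female heads), 0 (male heads, 30 with DESeq2) and 48 (male abdomens), and generation 2537 (male heads) and 1182 (male abdomens); the cause was not tested.

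With 2 surrogate variables the calls were 6 in F15 male heads, 1508 in F2 female abdomens, 104 in F5 male abdomens and 1112 for the difference in female heads, and CYP9AG7 turned to 0.80 for the difference in male abdomens. Without the low-count filter F5 male abdomens had 31 calls. On log2(TPM + 1) with limma-trend the calls were 32 (F5 male heads), 125 (F2 female abdomens), 536 (F5 male abdomens), 482 and 2 (difference, female and male heads), 2607 (generation, male heads) and 905 (generation, female abdomens). The sign turned for Fru at F2 in female heads (0.22), Dsx in F5 male heads (0.05) and Fru in F5 and F15 male abdomens (-0.05 and -0.02), none of them called; the cause was not tested. Medians over all tested genes moved on TPM from 0.099 to 0.2 (F14 female heads), -0.024 to 0.124 (F15 male heads), 0.061 to -0.097 (F5 male abdomens), 0.017 to 0.381 (generation, female heads), -0.074 to 0.147 (generation, male abdomens), 0.017 to -0.167 (sex, heads), 0.239 to 0.004 (difference, female abdomens), -0.248 to -0.127 (difference, male abdomens), -0.048 to 0.056 (difference, male heads) and 0.23 to 0.331 (tissue, females; 0.356 with DESeq2), and to 0.72 with DESeq2 for sex in abdomens.

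Without the 8 doubted libraries the calls were 88 and 9 in F5 and F15 male heads, 1834 in F2 female abdomens, 93 and 1186 in F5 and F15 male abdomens, 1189 (difference, female heads), 0 (difference, male heads), 142 (difference, male abdomens), 2345 (generation, male heads) and 631 (sex, heads). Of male heads 887 genes had an unadjusted p below 0.05 for the difference with all libraries. In F5 male abdomens the neural genes Dop2, nAChRa1 and nAChRa5 turned to -1.12, -0.54 and -0.34 once C46 was out; in F15 male abdomens Fru turned to -0.08, and CYP9AG7 to 2.91 for the difference in male abdomens. The cause was not tested beyond C46.

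With the Or1 covariate the calls were 403 and 471 in F2 and F14 female heads, 4 in F5 male heads and 2382 for generation in male heads. Or243 turned to 0.26 and Fru to 0.13 at F2 in female heads, Fru to -0.01 in F5 male heads and Dsx to -0.01 in F15 male heads; the covariate takes out what rises and falls with Or1, and the cause was not tested further. With an estimated correlation between genes 0 of 184 and 0 of 276 list tests passed, against 34 and 61 at the preset 0.01. In F5 male heads 1 pair of called genes had 1 tested gene between, 7.87 times the 0.127 expected (permutation p = 0.1), and 0 pairs were adjacent.

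Leaving out each library in turn gave these lowest and highest counts for ploidy: F2 female heads 1362 (C21) and 2125 (C35), F14 female heads 1358 (C62) and 2228 (C64), F5 male heads 7 (C55B) and 217 (C42), F15 male heads 2 (C94) and 315 (C91), F2 female abdomens 227 (C29) and 1773 (C30), F14 female abdomens 1037 (C69) and 5005 (C68), F5 male abdomens 2 (C60) and 864 (C48), F15 male abdomens 1423 (C87) and 2561 (C89). For the difference of effects they were 454 (C61) and 814 (C63) in female heads, 0 (C84; 30 with DESeq2 on all libraries) and 15 (C91) in male heads, 2687 (C69) and 5827 (C68) in female abdomens and 206 (C98) and 933 (C49) in male abdomens, and for generation in female abdomens 813 (C30) and 2902 (C68); the cause was not tested.

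Some genes changed sign on leaving out a library: Fru in F2 female abdomens from -0.10 (C39) to 0.13 (C29), Dsx in F5 male heads from -0.17 (C43) to 0.08 (C55B), Lop1 for the difference in male abdomens from -13.11 (C58) to 0.09 (C46), and in F5 male abdomens Dop2 from -1.12 (C46) to 4.62 (C58), nAChRa1 from -0.54 (C46) to 2.93 (C59) and nAChRa5 from -0.34 (C46) to 2.43 (C48). In F15 males SP76 in heads ran from -7.54 (C91) to 0.63 (C83), Dsx in heads from -0.12 (C94) to 0.14 (C83), Tra in heads from -0.15 (C93) to 0.46 (C84) and Fru in abdomens from -0.08 (C87) to 0.14 (C97). The median of the ion channel list in F5 male abdomens (1.58 with all libraries) was -0.38 without C46 and 1.57 without C69. Only Lop1 among the genes was called with all libraries; apart from C46, the cause was not tested.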

Other observations

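The correlations between detoxification genes and odorant receptors, the count of detoxification genes that differ between generations and the genes singled out by LOC symbol were chosen only after the result was seen.

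In female abdomens 4 genes were higher in triploids at both generations against the turn of the rest. LOC116415765 was at 24.4 ± 4.94 CPM in F2 triploids (n = 5) and 0.2 ± 0.172 CPM in F2 diploids (n = 4; log2 6.88, SE 0.77, adjusted p = 6.89e-06), was called at F14 (2.83, adjusted p = 0.016; without C79 2.49, adjusted p = 0.0596), and in F2 heads stood at 18 ± 3.99 against 0.958 ± 0.0607 CPM (4.22, SE 0.47, adjusted p = 3.34e-07). Calls of the other 3 ended at both generations on leaving out single libraries. In male abdomens LOC100115397 (0.69 and 1.21), LOC100119439 (0.80 and 0.82) and LOC100119452 (0.72 and 0.50) were called higher in diploids at F5 and F15 beside LOC100680350. Their F5 calls (adjusted p = 0.0474, 0.0449 and 0.0386) ended with the compared groups alone and without C57, C58, C59 or C60, and chance cannot be excluded for the F5 count. Of the genes tested in females, 72 were called in all 4 contrasts of ploidy: 64 were lower in both heads, lower in F2 abdomens and higher in F14 abdomens, and 8 were higher in both heads with the same turn in abdomens.

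In heads LOC100678896 was not called between diploid males and females (log2 -0.26, adjusted p = 0.0666). Nor was it between F14 triploid (19.3 ± 1.59 CPM, n = 4) and diploid females (log2 0.28, adjusted p = 0.136). In abdomens triploids were higher at F14 (log2 2.98, adjusted p = 0.0146) and not called at F2. LOC100680350 was not called between triploid and diploid females (log2 -0.24 and 0.12 in heads, -0.45 and 0.45 in abdomens, at F2 and F14).

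Detoxification genes and odorant receptors rose and fell together among heads of the same group. Over 35 heads, deviations of the mean log2 levels of both lists from their group means had r = 0.81 (permutation p = 2e-05, adjusted p = 6e-05; Spearman 0.69, permutation p = 6e-05, adjusted p = 0.00018; r = 0.76 without C93 and C43), and 6 relations were tested. Carboxylesterases (r = 0.88), P450 genes (0.74), glutathione S-transferases (0.70) and gustatory receptors (0.61) moved with the receptors, while ion channels did not (r = -0.10, permutation p = 0.6). With log2 Or1 as a covariate the median of the P450 genes at F14 went from -2.23 to -1.39 (7 lower genes left of 27), of the transferases from -1.40 to -1.28 (8 of 12) and of the esterases from -2.21 to -0.98 (2 of 6). At F2, where Or1 was as low (-3.74) and the receptors had a median of -3.14, the P450 genes were at 0.05 and the transferases at -0.13, and 25 of 65 detoxification genes (38.5%) were called lower at F14 than at F2 in the effect of ploidy. That percentage cannot decide whether less antennal RNA is the whole cause, since diploid heads differed in Or1 (139.6 CPM at F2, 357.6 at F14). A part in the variation within groups stays open, as a hypothesis found and tested on the same heads. Counting antennae or sequencing them apart would decide it.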
